A study of Mus musculus domesticus with 6 samples.

How the data were processed

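The study measured total RNA by sequencing in 6 samples of sorted mouse BFU-E at stage E14.5, 3 Cre-negative and 3 Cre-positive, all homozygous for a floxed Exosc3 gene per the labels. RNA was extracted with the Qiagen RNeasy Micro kit and libraries were made with Takara's SMARTer Stranded Total RNA-Seq kit in its Pico version, per the labels. Reads were processed with STAR 2.5.3a and RSEM 1.3.0 on the mouse build GRCm39 (mm39), per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here.

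Each deposited table holds 1 entry per gene with an expected count, the number of reads that RSEM's model assigns to the gene, per the file headers. The authors' tables also give TPM and FPKM, which are scaled for transcript length and library total, per the file headers. The mean and effective transcript length of each gene are deposited beside them. Each table had 55359 entries, of which 52081 matched a symbol by gene identifier without its version and 3278 did not. The reporter eGFP is among the unmatched and keeps its deposited name. Of all expected counts, 2.64% were not whole. They were rounded to whole numbers before testing, which changed no library total by more than 1e-05%. TPM and FPKM entered no test.

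Genes were kept by edgeR's filterByExpr with its defaults, which left 13117, and library sizes were scaled by TMM factors between 0.988 and 1.017. Cre-positive was tested against Cre-negative with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library sizes, and means are given with their SD over 3 libraries. Fold changes in the text are ratios of mean CPM. For a gene with 0 counts in all libraries of a group, the fold is a lower bound against a floor of 3 counts per library.

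The 33 gene lists were fixed before the data were examined. The 31 lists with at least 3 tested members were tested by limma's camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31, then again with an estimated correlation and by fry. Of the 8 that passed camera, only the p53 list held with an estimated correlation. Intervals of list medians are 95% bootstrap intervals over members, which treat genes as independent. Counts "adjusted over the list alone" use the same gene p-values adjusted within the list. Classes of uncharacterised gene models were compared by Fisher's exact test, two-sided, and with 10000 draws of genes matched on mean log2 CPM, one-sided toward fewer. Exact permutation tests are two-sided and cannot give a p under 0.1 with 3 against 3 libraries.

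Genes were named by a rule fixed in advance. Exosc3 came first. Among genes past the threshold with separated groups and a mean of at least 10 counts, the 8 largest rises and 8 largest falls with a characterised symbol were named, with 2 of each among uncharacterised models. From each list the members with the smallest p were named, 4 for 11 lists, 3 for the sort markers and 2 for every other list, and members of a list with none passing may be left out. Genes outside this rule are given as chosen after their values were seen. Genes with near-identical copies are given as uncertain.

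The labels number the embryos 1 to 3 within each genotype but do not say that a number marks a litter, so the numbers were not used as a block in the main test. Nothing in the labels excludes shared handling within a litter. Log2 CPM of the 6 libraries correlated at 0.778 to 0.832 between pairs, across genes, and no 2 libraries were close enough to be copies of 1 library. Xist was present and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had 0 counts in all 6 libraries.

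The total expected count per library was 96780246, 103891349 and 122278764 in the Cre-negative replicates 1, 2 and 3, and 124931215, 89629949 and 116126204 in the Cre-positive replicates. The common biological coefficient of variation was 85.4%. The median count of the 2095 genes seen in 1 library only was 108, taken here as the reads per captured molecule. Floors cover counting error of reads only. The tests were checked on 1 set of simulated counts for the same 13117 genes with the same means and library sizes and 200 changed genes. The counts were drawn from a negative binomial model with edgeR's own dispersion estimates, which may favour edgeR. They did not copy the reads per captured molecule, so the rates hold for that setting only. For this comparison edgeR recovered 48% of the 4-fold changes and 23% of the 2-fold changes, and 9% of its calls were unchanged genes. DESeq2 1.42.0 recovered 59% and 35%, and 47.5% of its calls were unchanged genes.

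Alternatives covered DESeq2's size factors, upper-quartile factors, library totals, removal of abundant noncoding and histone genes, 2 other filters, DESeq2, limma-voom, the replicate number as a block, effective lengths, GC content and length, stricter thresholds and each library left out in turn. Biotype, GC content and length came from GENCODE M21, an annotation of an earlier build, matched by gene identifier for 99.7% of tested genes. No coordinates are given, since that build is not the authors' build. Joins and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.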

Results

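RNA was sequenced from burst-forming erythroid progenitors (BFU-E, the earliest cells committed to making red blood cells) sorted from mouse fetal livers at stage E14.5. All embryos carried floxed alleles of Exosc3, which encodes a subunit of the RNA exosome, the complex that trims and degrades RNA from its 3' end. There were 3 libraries from Cre-negative embryos and 3 from Cre-positive embryos, in which the Vav1-Cre transgene drives recombination in blood cells. The design text places the 6 samples in 3 litters with 2 samples each. The libraries held between 89629949 and 124931215 expected counts. A gene seen in only 1 library had a median of 108 reads there, and reads were not counted by molecule. Floors therefore cover counting error of reads only, and a floor of 3 reads is less than the reads of 1 such molecule.

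Exosc3, the targeted gene (ENSMUSG00000028322), was measured first in every library. Its level was 51.9, 44.3 and 48.0 CPM (counts scaled to a common library size) in the Cre-negative replicates 1, 2 and 3, and 26.8, 22.1 and 30.2 CPM in the Cre-positive replicates 1, 2 and 3. The Cre-positive libraries thus held 54.9% ± 8.4 (SD, n = 3) of the mean Cre-negative level, and all 3 lay below all 3 Cre-negative libraries. The log2 fold change was -0.87 with a standard error of 0.22. It did not pass over all genes (adjusted p = 0.259, edgeR) or over the list of exosome genes alone (adjusted p = 0.0656), while DESeq2 called it (adjusted p = 0.00294, in a range of 0.00294 to 0.582 over the alternatives). A gene total also counts exons outside the floxed part, so transcripts of a recombined allele can still add to it. The other 21 tested exosome subunits and cofactors did not pass, and the list of 22 had a median log2 fold change of 0.00.

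A fluorescent reporter sequence counted beside the mouse genes separated the groups more widely. Reads assigned to eGFP, a green fluorescent protein, numbered 91, 0 and 197 in the Cre-negative replicates and 4884, 3311 and 4206 in the Cre-positive replicates. The means were 0.844 ± 0.798 CPM and 37.7 ± 1.45 CPM (SD, n = 3 each), a 44.7-fold difference with every Cre-positive library above every Cre-negative one. The log2 fold change of 5.48 became 6.32 without Cre-negative replicate 3. The exact permutation p was 0.1, the smallest that 3 against 3 libraries can give, and the adjusted p over all genes was 0.187 (edgeR). It was called by DESeq2 (adjusted p = 0.0321, in a range of 2.50e-05 to 0.53 over the alternatives). This reporter was singled out after its values were seen. The labels describe sorting of GFP-positive cells for all 6 samples and do not say how that gate was applied to Cre-negative embryos.

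**Figure D1:**
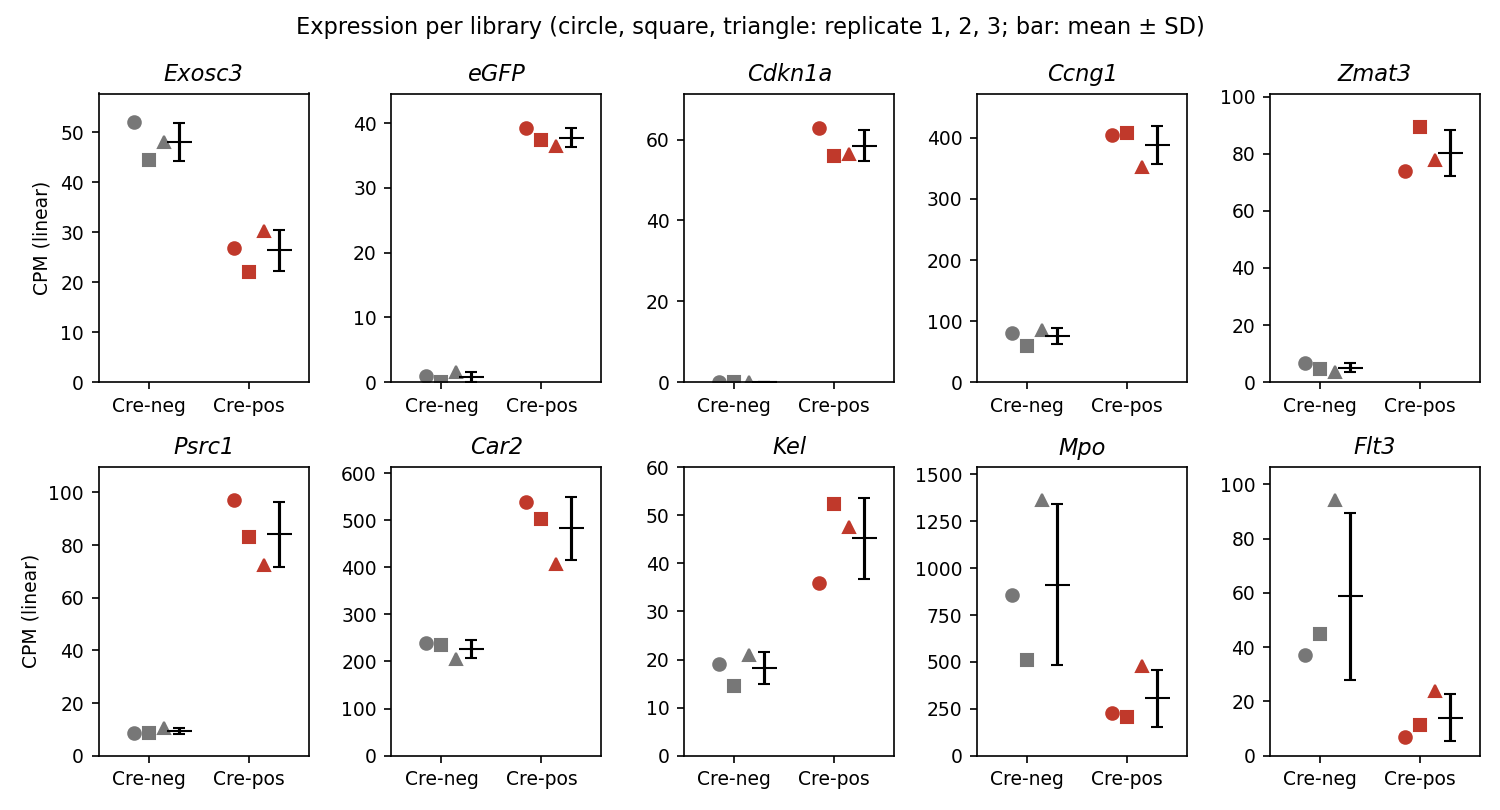
CPM of 10 genes on linear axes in 3 Cre-negative libraries (grey) and 3 Cre-positive libraries (red); circles, squares and triangles are replicates 1, 2 and 3, and the bars give mean ± SD. Exosc3 averaged 48.1 and 26.4 CPM, Cdkn1a had 0 counts in each Cre-negative library and 58.5 CPM in Cre-positive ones, and Mpo was lower in each Cre-positive library than in any Cre-negative one.

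The comparison of Cre-positive with Cre-negative BFU-E asks how gene expression differs when Exosc3 is targeted in the progenitors. The 4 rises with the smallest p were in Cdkn1a, Ccng1 and Zmat3, which are on the list of p53 target genes, and in Psrc1, which is not. The list holds 28 genes, and absence from it does not show that a gene is not a p53 target. Cdkn1a, the cell cycle inhibitor p21, had 0 counts in each Cre-negative library and 58.5 ± 3.89 CPM (SD, n = 3) in Cre-positive libraries. Against a floor of 3 counts per library it was at least 2091-fold higher. That floor covers read counting only, and 1 missed molecule, taken as 108 reads, would exceed it. The log2 fold change of Cdkn1a was 15.6, and 8.88 at its lowest over the alternatives. Ccng1, which encodes cyclin G1, rose 5.17-fold, from 75.1 ± 13.3 to 388 ± 31.5 CPM. Zmat3, a zinc finger RNA-binding protein, rose 16.0-fold, from 5.03 ± 1.63 to 80.3 ± 8.03 CPM, and Psrc1, a microtubule-binding protein gene, rose 9.08-fold, from 9.27 ± 1.09 to 84.2 ± 12.4 CPM.

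Of 13117 genes tested, 16 were higher and 0 were lower in Cre-positive cells at an adjusted p under 0.05 (edgeR). With the replicate number as a block edgeR called 56 genes, 38 of them higher and the rest lower. At the same adjusted threshold limma-voom called 20 higher, 12 of the 16 among them, and 0 lower, and DESeq2 called 316 higher and 303 lower. At an unadjusted p under 0.05 edgeR gave 531 higher and 549 lower genes. Cpt1c, a brain-type carnitine palmitoyltransferase, had 4 reads in 1 Cre-negative library and none in the other 2, against 24.3 ± 1.45 CPM in the Cre-positive libraries. Zfp365, a zinc finger gene, and Sulf2, an extracellular sulfatase, had 0 counts in each Cre-negative library. Zfp365 had 1893, 1230 and 1837 reads in the Cre-positive replicates, and Sulf2 averaged 12.7 ± 8.53 CPM there (SD, n = 3). They were at least 537-fold and at least 453-fold higher against the same floor, which covers read counting only. The bound for Sulf2 fell to at least 285-fold without Cre-positive replicate 3, its highest library. The log2 fold change of Zfp365 was 13.7, and 6.94 at its lowest over the alternatives. Sulf2 had too few counts to be tested per molecule. Mpp1, which encodes a membrane scaffold protein of red cells, rose 4.42-fold, from 24.9 ± 4.04 to 110 ± 19.4 CPM. The other 8 calls had smaller rises and, apart from Car2, are named after their values were seen. They were Cd55 (3.88-fold), Gja1 (3.73-fold), Gtse1 (3.09-fold), Exoc4 (2.67-fold), Cd81 (2.14-fold), Car2 (2.13-fold), Rev1 (1.91-fold) and Gtf3c1 (1.73-fold).

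Each of the 16 called genes was higher in 3 of 3 Cre-positive libraries than in any Cre-negative library. Over all tested genes the groups were separated, in either direction, for 15.2%, where chance gives 10%. By limma-voom Cdkn1a (adjusted p = 0.178), Cpt1c (0.312), Zfp365 (0.278) and Sulf2 (0.454) lost their calls. Effective length offsets kept 6 of the 16 calls (Cdkn1a, Ccng1, Psrc1, Zmat3, Cpt1c and Zfp365) and took Cd55 from 1.96 to 1.33 on the log2 scale (adjusted p = 0.382). Among genes with a mean of at least 1000 counts, a filter chosen after the data were seen, edgeR called 58 higher and 26 lower. Without Cre-positive replicate 1 the higher calls numbered 8, and without Cre-positive replicate 2 they numbered 7. Calls of 7 genes (Cdkn1a, Ccng1, Psrc1, Zmat3, Exoc4, Mpp1 and Cpt1c) held without each library in turn. Car2 lost its call without Cre-positive replicate 1 or 2 (highest adjusted p = 0.0850), and Zfp365 without any 1 Cre-positive library (0.0831). Gtse1 lost its call without Cre-negative replicate 3 or any 1 Cre-positive library (0.107). Cd55 kept its call only without Cre-negative replicate 1, Gja1 only without Cre-negative replicate 3 and Rev1 only without Cre-positive replicate 3 (highest adjusted p = 0.166, 0.144 and 0.158). Cd81, Gtf3c1 and Sulf2 lost theirs without any 1 of the 6 libraries (0.159, 0.158 and 0.158).

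Among 27 tested p53 target genes, 3 (Cdkn1a, Ccng1 and Zmat3) passed over all genes and 19 were higher adjusted over the list alone. None was lower by either count, and 23 of 27 had a positive log2 fold change. The median log2 fold change was 1.68 (95% bootstrap interval 1.05 to 3.54). Setting the 2 members at 0 in Cre-negative libraries to their bounds against the floor of 3 counts per library left it at 1.68. Both of these bounds lie above the median. That floor covers read counting only and is less than the reads of a captured molecule. Whether the median would move with bounds that allow for a missed molecule was not tested. The list stood above other genes by camera (adjusted p = 7.9e-22), and it was the one list that held with an estimated correlation (adjusted p = 0.0113). Pmaip1, which encodes the apoptosis inducer Noxa, was 6.98-fold higher (23.5 ± 5.52 against 3.36 ± 1.03 CPM) with an adjusted p of 0.0598 over all genes and 0.000583 over the list alone. Over all genes with the replicate number as a block its adjusted p was 0.0481 (edgeR). Trp53 itself, tested among DNA damage response and repair genes, had a log2 fold change of 0.21 with a standard error of 0.09 and did not pass.

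Pro-apoptotic genes were split. Of 26 tested, none passed over all genes, and 5 were higher adjusted over the list alone (Pmaip1, Bax, Bbc3, Fas and Tnfrsf10b, the last named after its values were seen). All 5 are also on the p53 list. Bax, a pore-forming BCL2 relative, was 2.33-fold higher at 59.1 ± 11.2 against 25.4 ± 4.89 CPM, and Bbc3, which encodes Puma, was 11.6-fold higher at 21.7 ± 11.6 against 1.86 ± 1.54 CPM. The log2 fold change of Bbc3 was 3.54, and 4.47 without Cre-negative replicate 3. The list did not pass camera (adjusted p = 0.0838), where its direction was up while its median log2 fold change was -0.01, and it passed fry, which does not compare it with other genes (adjusted p = 0.0236). Of 12 anti-apoptotic genes none passed by either count, and Bcl2 had the smallest p, with a log2 fold change of -1.43 and a standard error of 0.42.

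Genes of the red cell lineage were higher as a group. Car2, carbonic anhydrase 2, rose from 226 ± 18.8 to 483 ± 67.3 CPM (SD, n = 3; adjusted p = 0.00787, edgeR) and was the 1 of 25 tested erythroid genes that passed over all genes. Adjusted over the list alone, 4 were higher. Car2 was among them, as were Sptb (2.03-fold), which encodes a protein of the red cell membrane skeleton, and Kel (2.49-fold), a blood group antigen. Sptb also passed over all genes with the replicate number as a block (edgeR adjusted p = 0.00739), and Kel did not. The list passed camera upward with a median log2 fold change of 0.46 (adjusted p = 4.35e-05), but not with an estimated correlation (adjusted p = 0.734). Of the globin genes 3 had enough counts to be tested and none passed, and heme synthesis genes did not pass (adjusted p = 0.0827, median log2 fold change 0.22).

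Neutrophil and monocyte markers and lymphoid markers were lower as groups. Of 11 tested neutrophil and monocyte markers none passed over all genes and 5 were lower adjusted over the list alone, among them Mpo, the myeloperoxidase of granules, and Spi1, the transcription factor PU.1. Mpo averaged 912 ± 429 CPM in Cre-negative and 305 ± 152 CPM in Cre-positive libraries, and Spi1 averaged 34.0 ± 11.9 and 13.9 ± 2.55 CPM (SD, n = 3 each). The log2 fold change of Spi1 was -1.29, and 0.01 with effective length offsets. With the replicate number as a block Mpo passed over all genes (adjusted p = 0.000868). The list median was -1.50 on the log2 scale (camera adjusted p = 0.000193, and adjusted p = 0.605 with an estimated correlation). Of 10 lymphoid markers 2 were lower adjusted over the list alone, Ighm (32.6 ± 17.4 against 1.06 ± 1.24 CPM) and Il7r (10.6 ± 4.42 against 1.55 ± 1.14 CPM). Single libraries moved both: the log2 fold change of Ighm was -4.95, and -6.39 and -4.36 without Cre-positive replicates 2 and 3, while that of Il7r was -2.78, and -3.58 without Cre-positive replicate 3. The lymphoid median was -2.57 (camera adjusted p = 0.000193, and adjusted p = 0.302 with an estimated correlation). Too few lymphoid markers had a mean of at least 1000 counts for a list test there. Dropout of genes with few captured molecules was therefore not tested for this list.

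Stem and multipotent progenitor markers were lower too, by a median of -0.27 over 20 genes (camera adjusted p = 0.0485, and adjusted p = 0.768 with an estimated correlation). None passed over all genes, and 2 were lower adjusted over the list alone. These were Hmga2, a chromatin protein of fetal stem cells, at 58.0 ± 27.1 against 152 ± 45.9 CPM, and Flt3, a cytokine receptor of early progenitors, at 14.0 ± 8.67 against 58.7 ± 30.9 CPM. The log2 fold change of Flt3 was -2.07, and -2.69 without Cre-positive replicate 3. Both genes passed over all genes with the replicate number as a block (adjusted p = 0.00632 for Hmga2 and 0.0105 for Flt3). Of the sort markers, Kit, Cd24a and Tfrc had log2 fold changes of -0.19, 0.53 and 0.04, and none passed. BFU-E regulators did not pass camera (adjusted p = 0.922). One of 18, Csf2rb2, was lower adjusted over the list alone, from 3.12 ± 1.59 CPM to 0 counts in each Cre-positive library, and its near-identical paralog Csf2rb makes its counts uncertain.

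**Figure D2:**
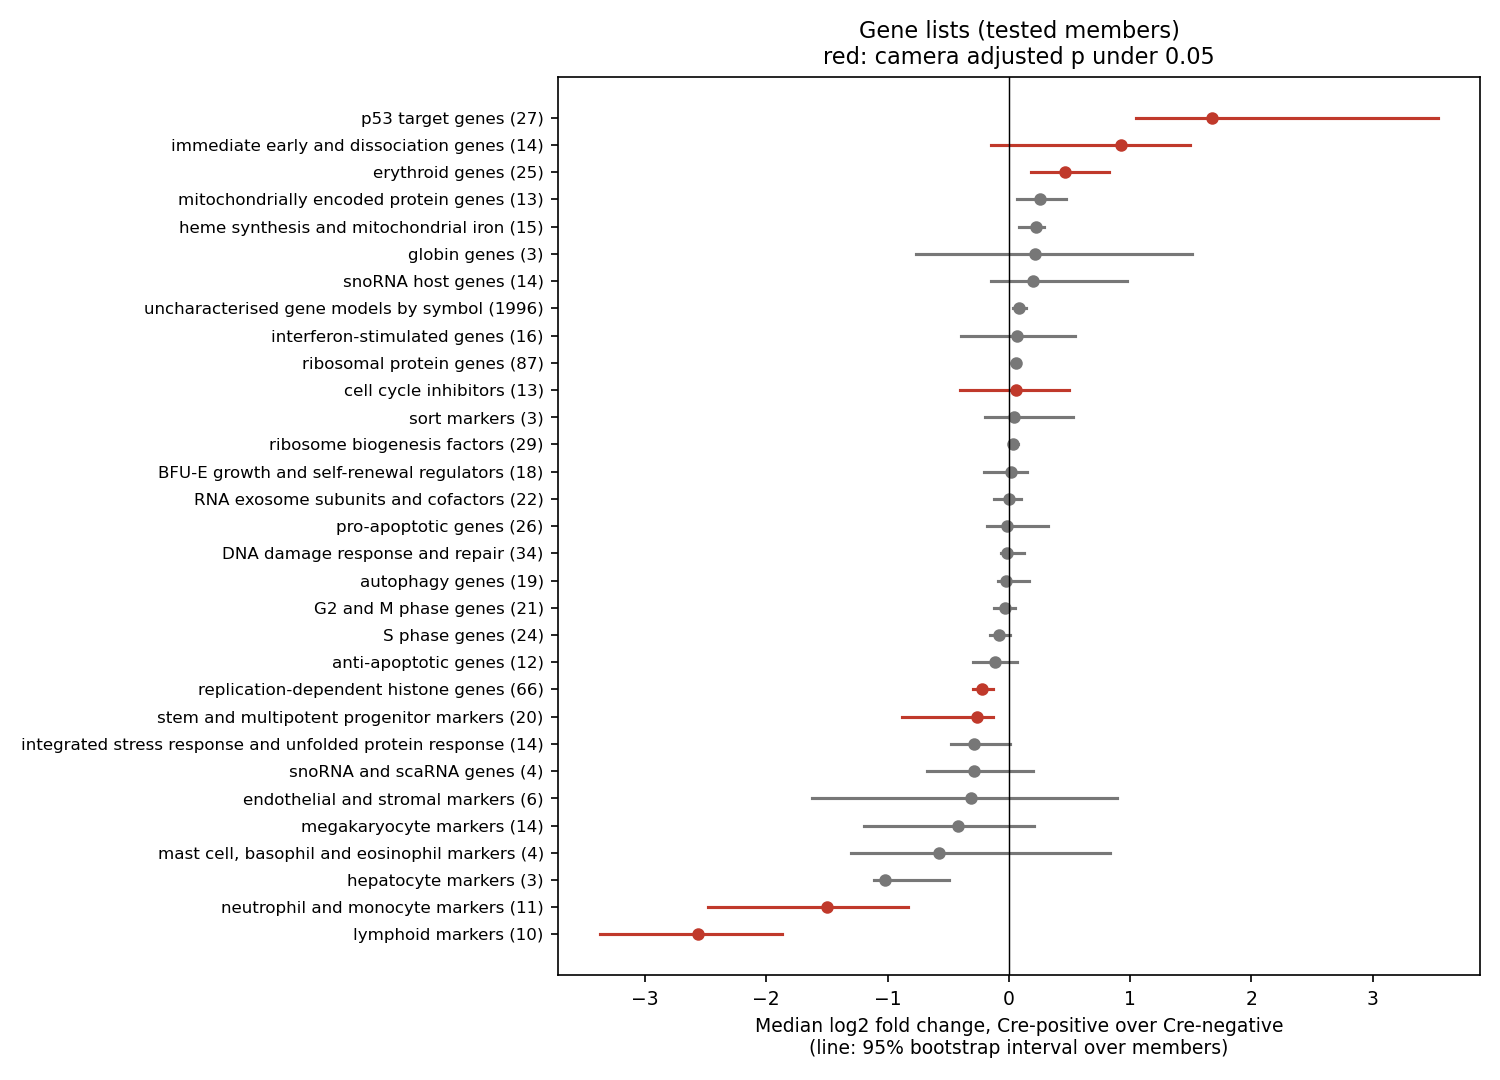
Median log2 fold change of Cre-positive over Cre-negative for 31 gene lists (tested members in parentheses), with 95% bootstrap intervals over members; red marks the 8 lists with a camera adjusted p under 0.05. The p53 targets lie farthest to the right at 1.68 and the lymphoid markers farthest to the left at -2.57.

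Histone genes were lower as a group, and immediate early genes were higher. Of 66 replication-dependent histone genes, whose near-identical copies make single genes uncertain, 51 had a negative log2 fold change, with a median of -0.22 (camera adjusted p = 0.00101, and adjusted p = 0.768 with an estimated correlation). None passed by either count, and Hist1h2bm had the smallest p (281 ± 7.74 against 190 ± 37.2 CPM). Immediate early and dissociation genes had a median of 0.92 over 14 genes (camera adjusted p = 0.0117, and adjusted p = 0.768 with an estimated correlation). None passed over all genes, and Jun, a subunit of the AP-1 transcription factor, was higher adjusted over the list alone (97.7 ± 17.9 against 34.6 ± 15.5 CPM). Jun did pass over all genes with the replicate number as a block (edgeR adjusted p = 0.0414). Cell cycle inhibitors passed upward (camera adjusted p = 0.0485, and adjusted p = 0.605 with an estimated correlation) with a median of 0.06 over 13 genes, and did not pass by ranks (adjusted p = 0.346) or with the replicate number as a block (adjusted p = 0.183). Cdkn1a passed over all genes, and adjusted over the list alone 3 were higher, Rb1 (2.01-fold) among them, and 1 was lower.

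The p53, erythroid, neutrophil and monocyte, and lymphoid lists kept their calls without each library in turn, and the other 4 did not. Stem markers lost theirs without Cre-negative replicate 1 (adjusted p = 0.0502), Cre-negative replicate 3 (0.721), Cre-positive replicate 1 (0.193) and Cre-positive replicate 2 (0.423). Histone genes lost theirs without Cre-negative replicate 1 (0.0607), Cre-positive replicate 2 (0.0652) and Cre-positive replicate 3 (0.115). Immediate early genes lost theirs without the same libraries (0.0821, 0.0958 and 0.0700), and cell cycle inhibitors without Cre-negative replicate 2 (0.579) and Cre-positive replicates 1, 2 and 3 (0.0532, 0.0958 and 0.116).

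In all, 23 tested lists did not pass camera, with adjusted p from 0.0827 to 0.922. Among markers of other cells, the medians were -0.42 for megakaryocytes, -0.58 for mast cells, basophils and eosinophils, -1.02 for hepatocytes and -0.31 for endothelial and stromal cells. Medians for the cell cycle were -0.08 in S phase genes and -0.03 in G2 and M phase genes. Those for stress and turnover were -0.29 in the integrated stress and unfolded protein response, 0.07 in interferon-stimulated genes, -0.02 in autophagy genes and -0.02 in DNA damage response and repair. Genes of the translation machinery had medians of 0.03 for ribosome biogenesis factors and 0.06 for ribosomal proteins. The median was 0.20 in snoRNA host genes, -0.29 in 4 snoRNA and scaRNA genes and 0.26 in mitochondrially encoded protein genes. Macrophage markers and structured small RNAs each had 1 tested member, which is too few for a list test.

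Transcripts without a known protein were asked about because the exosome degrades many of them. Uncharacterised gene models stood in for them. That class is set by the form of the symbol, such as Gm with a number or an ending in Rik. It is not defined by coding status and leaves out named noncoding RNAs such as Malat1. None of the 16 higher calls was an uncharacterised gene model, a class that makes up 15.2% of tested genes (Fisher's exact p = 0.154, two-sided). Against genes of matched expression the permutation p for so few was 0.504, one-sided. With the replicate number as a block 0 of 38 higher calls were in the class (exact p = 0.00276), while DESeq2 had 61 of 316, or 19.3% against 17.2% of the genes it tested (exact p = 0.327). Neither of these comparisons was matched on expression. The class as a whole had a median log2 fold change of 0.08 over 1996 genes and did not pass camera (adjusted p = 0.532). By annotation, genes with a biotype other than protein coding made up 15.3% of tested genes and 0 of the 16 higher calls (Fisher's exact p = 0.154, two-sided).

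By summed counts, 8 of 17 annotation classes and single RNAs had separated groups, all 8 with every Cre-positive library above every Cre-negative one, where chance separates 10% in either direction. These classes overlap and were chosen after the values were seen. Long intergenic noncoding RNA genes took 0.658% ± 0.0495 of counts in Cre-negative and 0.850% ± 0.119 in Cre-positive libraries (SD, n = 3 each). Antisense genes took 0.145% ± 0.00672 and 0.194% ± 0.0200, of which the imprinted RNA Kcnq1ot1 alone took 0.0662% ± 0.0103 and 0.102% ± 0.0200. Without it the antisense shares were 0.0785% ± 0.00368 and 0.0920% ± 0.00331. The nuclear RNA Malat1 took 0.274% ± 0.0253 and 0.364% ± 0.0459. Each gave an exact permutation p of 0.1, the smallest possible for 3 against 3 libraries, and 0.213 after adjustment over the 17. The strand setting of the counting is not given in the sources used here, so antisense reads cannot be told from those of the overlapping gene.

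**Figure D3:**
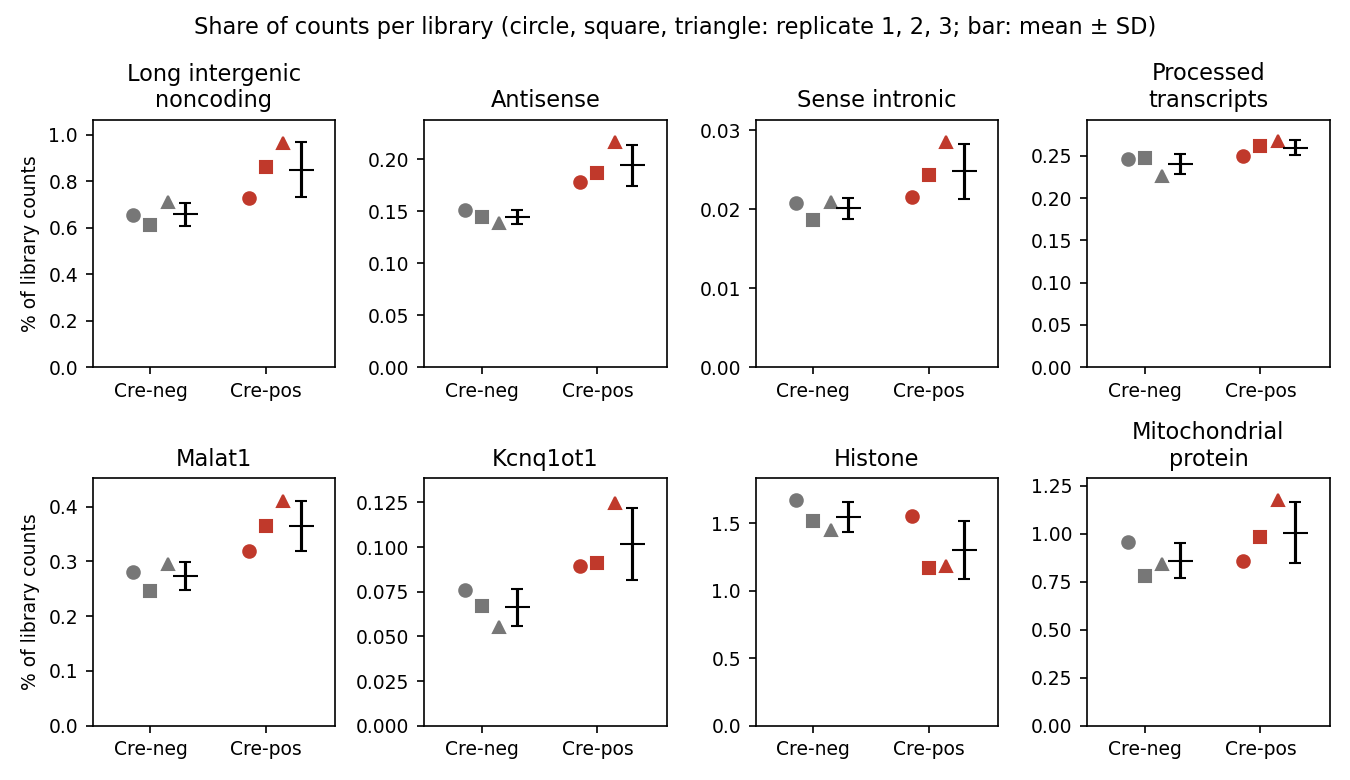
Share of each library's counts, in percent on linear axes, taken by 6 annotation classes and 2 single RNAs in 3 Cre-negative (grey) and 3 Cre-positive (red) libraries; symbols are replicates 1, 2 and 3 and bars give mean ± SD. Long intergenic noncoding RNAs averaged 0.658% and 0.850%, while histone and mitochondrial protein genes overlapped between the groups.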

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

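The filter on a mean of at least 1000 counts, counts divided by reads per molecule, camera on ranks, list tests with GC and length offsets and the class of DESeq2's calls were chosen after the data were seen. Every alternative chosen beforehand was run. The 16 higher calls kept their direction in every alternative that tested them, and 7 of them (Cdkn1a, Ccng1, Psrc1, Zmat3, Exoc4, Mpp1 and Cpt1c) stayed called without each library in turn. Other normalizations, GC and length offsets, the block, no filter, the stricter CPM filter and DESeq2 kept all 16, while limma-voom lost Sulf2, Cpt1c, Cdkn1a and Zfp365 and effective length offsets kept 6. The count of higher genes was 33 with no filter, 316 by DESeq2, 38 with the replicate number as a block, 6 with effective length offsets, 32 with GC and length offsets and the block together, 9 at an adjusted p under 0.01, 58 at a mean of at least 1000 counts and 69 per molecule. Leaving out 1 library gave 7 to 15. Lower genes numbered 0 in the main test, 6 with no filter, 3 with a CPM of at least 1, 303 by DESeq2, 18 with the block, 14 with GC and length offsets and the block, 26 at a mean of at least 1000 counts, 34 per molecule and 0 to 3 without 1 library. The cause was not tested.

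Libraries with the same number deviated together only weakly, with correlations of 0.026, 0.053 and 0.073. Values this low do not exclude pairing. The labels do not say that a number marks a litter, so the numbers were not taken to pair the samples. Each library did correlate best with its own number, a hint from the data and not from the design. With the block all 16 higher calls were kept, and 7 of the 8 lists that passed camera. Cell cycle inhibitors were the list lost with the block (adjusted p = 0.183) and by ranks (0.346).

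Exosc3 ranged from -0.98 to -0.75 on the log2 scale and passed only by DESeq2 (-0.87, adjusted p = 0.00294), with adjusted p from 0.00294 to 0.582 over the alternatives. The number of lists passing, 8 in the main test, was 1 with an estimated correlation and 3 by fry (2 of the 8, p53 targets and cell cycle inhibitors, and the pro-apoptotic list), and 4 to 9 without 1 library, the fewest without Cre-positive replicate 2. Of uncharacterised gene models among higher calls, the share was 0% in the main test, below the 15.2% of tested genes, and 0% to 12.5% without 1 library. With the block it was 0% of 38 calls and the difference from all tested genes passed (exact p = 0.00276), but expression was not matched in that comparison. By DESeq2 the share was 19.3%, above the 17.2% of genes tested there. P ranged from 0.00276 to 1 over the alternatives. Over 69 other named genes, 1183 of 1364 values stayed on the same side of the threshold and 121 gained a call, while 56 lost one. Spi1 and Gins1 changed sign with effective length offsets (0.0093 and 0.054), and Tfrc did without Cre-negative replicate 3 (-0.16) and without Cre-positive replicate 2 (-0.29), in a range of -0.29 to 0.23. The cause was not tested. No scaling moved the median log2 fold change of all genes by more than 0.1.

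DESeq2 called 619 genes against 16 by edgeR. One explanation is that DESeq2 takes the spread of genes with few captured molecules as too small. Over the other 9 splits of the 6 libraries DESeq2 still called a median of 108 genes (71 to 271), which is 17.4% of 619. That lies between the bounds set beforehand, so the explanation could be part of the difference and cannot be told apart from real changes. Those splits mix the genotypes within their groups, so their calls do not show what DESeq2 would give without a genotype difference.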

Other observations

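The tests on dropout, on GC content and length, on maturity, on granulocytes, on macrophages or monocytes, on the sort gate, on noncoding classes and on calls among genes with a mean of at least 1000 counts were chosen after the results were seen. Among the 8338 genes with a mean of at least 1000 counts, 58 were higher and 26 lower in Cre-positive cells (edgeR), and 13 of these 84 calls were p53 target genes, all higher. They added Plk2, a p53-induced kinase, with 31 reads over the Cre-negative and 11248 over the Cre-positive libraries, Sesn2 (3.20-fold), a stress-induced inhibitor of growth signalling, and Mdm2 (2.07-fold), the ubiquitin ligase that degrades p53. All 31 Cre-negative reads of Plk2 lay in replicate 1. Without that library the log2 fold change of Plk2 in the main test went from 8.4 to 14.9. The DNA repair nuclease gene Ercc5 had a log2 fold change of 1.82. The lower calls included Mn1 (22.3 ± 11.2 against 2.24 ± 0.852 CPM) and Satb1 (61.0 ± 21.5 against 19.3 ± 4.69 CPM; SD, n = 3 each). The nuclear RNAs Malat1 (1.35-fold) and Kcnq1ot1 (1.56-fold) were also called there, each with an adjusted p of 0.0290, in ranges over the alternatives of 0.000166 to 0.571 and 0.0104 to 0.54. These genes were picked from that list after their values were seen.

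Of 7 noncoding classes tested in the same set of genes, 4 passed camera upward and none did with an estimated correlation. Of 37 long intergenic noncoding genes 26 had a positive log2 fold change (adjusted p = 0.0332), and of 17 antisense genes 11 did (adjusted p = 0.0332), where 49.7% of all genes in the set were positive. Processed transcripts (adjusted p = 0.0378) and 3 sense intronic genes (adjusted p = 0.0392) also passed. With an estimated correlation the adjusted p of these 4 was 0.124 to 0.144. Unconfirmed gene models (adjusted p = 0.212), bidirectional promoter genes (0.48) and processed pseudogenes (0.547) did not pass. Over all tested genes, antisense genes passed (adjusted p = 0.0296, and 0.139 with an estimated correlation) and long intergenic noncoding genes did not (adjusted p = 0.319).

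The rise of p53 target genes was weighed against technical explanations. Dropout of genes with few captured molecules is argued against as the whole cause by the 12 members with a mean of at least 1000 counts in the Cre-negative libraries. They stood above other genes so chosen, with a median log2 fold change of 1.02. The camera p was 8.40e-12, and 0.00196 with an estimated correlation. For members with fewer Cre-negative counts dropout was not tested. GC content or length bias is argued against, since 529 genes outside the list nearest to its members in GC content and length had a median of 0.004 (95% bootstrap interval -0.035 to 0.042). Another cell type in the Cre-positive sort would bring its own markers. The lists compared were the megakaryocyte, neutrophil and monocyte, mast cell, basophil and eosinophil, lymphoid, hepatocyte, and endothelial and stromal markers. The highest median among these lists was -0.314 (endothelial and stromal), and their highest upper limit of 0.894 lay below the lower limit of 1.05 for p53 targets. Stem and multipotent progenitor markers, with a median of -0.27, were left out of that comparison. Erythroid genes were left out too, and they were higher, with a median of 0.46 (95% bootstrap interval 0.19 to 0.83). A different stage of red cell maturation in the Cre-positive sort was therefore not tested by that comparison. Handling or dissociation stress stays open: immediate early genes had a median of 0.923, whose upper limit of 1.497 lies below the p53 median of 1.68, the bound set beforehand against this explanation. That bound left out the spread of the p53 median, and the difference of 0.754 between the medians has an interval of -0.037 to 2.66, which includes 0. Loss of Exosc3 may raise p53 activity, but Cre and eGFP go with genotype in all 6 libraries, so an effect of Cre itself was not tested.

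Lower myeloid and lymphoid markers came with higher erythroid genes. Mature granulocytes among the Cre-negative cells are argued against, since S100a8, S100a9, Camp and Ngp together reached 0% of the Mpo level there, with 0 CPM against 919 CPM on library totals, or 1.37% with Lyz2 (12.6 CPM) added. Macrophages or monocytes stay open. The 16 macrophage markers fixed beforehand summed to 3.29 CPM in Cre-negative and 0.833 CPM in Cre-positive libraries, and Mpeg1, a macrophage and monocyte gene chosen after its values were seen, had 10.2 ± 6.16 CPM in Cre-negative and 0 counts in Cre-positive libraries. A lineage-negative sort would remove many such cells. The gap between mean log2 erythroid and mean log2 stem, myeloid and lymphoid levels was 3.82 ± 0.756 in Cre-positive and 2.01 ± 0.926 in Cre-negative libraries (SD, n = 3 each; exact permutation p = 0.1, the smallest possible). These lists had already been found to differ in the same libraries, so the separation of the gaps restates those differences. A difference in maturity between embryos or litters cannot be told apart from genotype, since the lowest Cre-positive gap lay above the highest Cre-negative one by 0.203, less than the SD within either group, and the labels do not say which embryos share a litter. Libraries of the same number differed by 1.62 to 1.98 in this gap, Cre-positive higher each time. A sort gate placed at a different stage also stays open, with Tfrc at 0.041 and Cd24a at 0.53 against the erythroid median of 0.46. These are RNA levels, while a gate acts on protein, so they cannot show where the gate was placed. How the GFP gate was applied to Cre-negative embryos is not given either.

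There are only 10 splits of the 6 libraries into groups of 3, too few for a share under 0.05. Every split but the real one mixes the genotypes within its groups, where a genotype difference adds to the spread. Low counts there do not show what the absence of a genotype difference would give. The real split gave 16 calls by edgeR and the highest of the others 0, with 1 of 10 splits reaching the real value. For genes with a mean of at least 1000 counts these values were 84 and 1, and for lists passing camera 8 and 6.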
